A study of Mus musculus with 6 samples.

How the data were processed

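The files came from 6 two-colour Agilent arrays, 3 per group, each with the MeDIP DNA of a sample in Cy5 and its input DNA in Cy3, per the labels' protocols. Per the file headers, the authors scanned each array and extracted it with Feature Extraction 11.0.1.1 and the protocol ChIP_1100_Jul11, with positions in the mm9 build. The processed signals are intensity values that were background-subtracted and multiplied by a linear dye factor per channel, per the file headers. The files also hold a log10 ratio of red over green, per the file headers, which equalled the log10 ratio of the processed signals within 0.0001 at 99.0% of the spots. The authors' deposited table of the whole series holds a score per probe. It correlated at 0.87 to 0.91 with the log2 ratio of the processed signals of the same array, so its direction is the same, but its log base, scale and centring are not known. Its medians per array were 0.061, 0.057 and 0.043 in the inulin group and 0.056, 0.054 and 0.054 in the obesity group. How that table was made is not given in the sources used here.

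The main values were log2 of the red over the green processed signal, with spots marked as outliers left out (1901 to 4863 per array) and each array centred on its median over the probes that are not controls. No loess or quantile step was used, because most probes of such an array carry signal. Regions were runs of probes whose starts lay at most 500 bp apart on a chromosome, with at least 3 probes, and a region's value was the mean of its probes. Probes and regions needed values on at least 2 arrays of each group. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are inulin minus obesity. Single values per array were compared by exact permutation tests. Figures were drawn with matplotlib 3.10.9.

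The regions named are the 10 per direction with the largest difference among those past the threshold, and the probes named are the 3 per direction with the lowest p. This rule, the tests of probes, regions, spread and sex chromosomes, and most alternatives were fixed before the data were examined. The tests by chromosome and by window, and the sets of regions ordered by mean ratio, were not part of that plan. The rule also passed over regions without a gene name, a clause that had no use because no region here has one. The array files pair no probe with a gene, and the gene table at hand describes another build than mm9. Gene values, the 24 gene lists, probe classes and the genes to be named in every case were therefore not analysed here.

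Slide and position were taken from the file headers. Since each slide held arrays of 1 group and the obesity group spanned 2 slides, slide entered as a random block. The test without a block and the test with slide as a random block were tested on simulated data made from the real means and spreads, and the other alternatives were not. The simulations held 200 changed regions or probes in equal numbers at log2 shifts of 0.5, 1, 2 and 3. With no slide effect, the region test recovered 41 of 50 at a shift of 0.5 and 50 of 50 at each larger shift among 22572 regions, and 4.95% of the unchanged regions had an unadjusted p under 0.05. The probe test recovered 0 of 50 at 0.5, 20 at 1, 50 at 2 and 49 at 3 among 161716 probes. The random block did not correct a simulated slide effect in this layout. Its correlation was estimated at -0.17, 0.0087 and 0.19 for simulated slide correlations of 0, 0.3 and 0.5, and 9.51%, 12.8% and 13.4% of the unchanged regions had an unadjusted p under 0.05. Without the block this share was 13.0% and 20.2% at slide correlations of 0.3 and 0.5.

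The alternatives were normexp background correction on the median spot signals (offset 50; the files hold no mean spot signal), loess within arrays, equal scale, quantile normalization, the authors' deposited table, a filter on dim input, blocks for replicate number and slide, array weights, a robust prior with a trend, the autosomes alone, a threshold of 0.1, gaps of 300 and 1000 bp, the median of the probes, and leaving out each array. Array weights were estimated by REML on complete rows. A block for the position on the slide, a filter on both channels, each channel alone, equal scale with slide, and array weights by a gene-by-gene estimate were chosen after the data were seen.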

Results

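DNA methylation was measured in the hypothalamus, the brain area that governs feeding and energy balance, of 16 week old mouse offspring. Methylated DNA was enriched by immunoprecipitation with an antibody (MeDIP) and hybridised with the input DNA of the same sample to a two-colour tiling array. There were 3 arrays from offspring of dams given inulin, a fermentable plant fibre, and 3 from offspring of obese dams, whose labels also name a high fat diet. The array carried 174638 probes of 45 to 60 bp outside the controls. In the mm9 build, 22574 regions held 3 or more neighbouring probes, with a median of 8 probes and 1617 bp. The input signal was well above background at 94.4% to 96.4% of the probes of each array, and the MeDIP signal at 77.3% to 85.7%. The number of arrays limits the precision of every value. The labels do not say whether the samples came from separate litters, so the p-values measure the spread between these samples only.

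The first comparison asked at which regions the MeDIP over input ratio differed between the offspring of inulin dams and of obese dams. By limma with Benjamini-Hochberg adjustment, 1675 of 22574 regions passed the adjusted threshold of 0.05, of which 1267 had a higher ratio in the inulin group and 408 a lower one. The median difference, inulin minus obesity on the log2 scale, was 0.45 for the higher regions and -0.35 for the lower regions. At an unadjusted p under 0.05 there were 6448 regions. The groups did not overlap at 7895 regions (35.0%), where chance gives 10%. These calls cannot be separated from the slides. All 3 inulin arrays lay on slide 1, obesity arrays 1 and 3 on slide 2 and obesity array 2 on slide 3, so no slide held both groups. With slide as a random block (limma, estimated correlation 0.29), 0 regions passed and 4049 had an unadjusted p under 0.05. In simulated data with 200 changed regions, the test without slide called 207 regions at a slide correlation of 0, 334 at 0.3 and 891 at 0.5, of which 16, 138 and 693 were unchanged. With slide as a random block, 126 of 322 calls at 0.3 and 130 of 325 at 0.5 were unchanged regions. In these simulations the block estimated the correlation at only 0.0087 and 0.19. The 0.29 of the real data lies above both, so the simulated settings may understate the slide effect. They set no upper bound on the share of unchanged regions among the 1675. Leaving out inulin array 1, 2 or 3 left 0 regions past the threshold by limma, with 4704, 4314 and 5428 at an unadjusted p under 0.05. Without obesity array 1 there were 952 regions and without obesity array 3 there were 632. Leaving out obesity array 2, the only one on slide 3, raised the count to 2171, in a fit with 1 slide per group.

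The excess of higher calls depended on the processing of the arrays. Higher and lower regions numbered 1267 and 408 with median centring, 1908 and 890 with loess, 485 and 426 with the arrays on an equal scale, and 251 and 246 after quantile normalization. They numbered 1027 and 894 with normexp background correction, and 248 and 334 in the authors' deposited table, whose scale is not stated. Over probes well above background in both channels, a filter chosen after the data were seen, they numbered 619 and 732. With median centring the regions called higher lay mostly among regions of low ratio. Among 5 equal sets of regions ordered by mean ratio, the lowest set held 801 higher and 11 lower calls, and the highest held 12 higher and 241 lower calls. The median difference was 0.21 in the lowest set and -0.087 in the highest. On an equal scale it was -0.039 in the lowest set and 0.052 in the highest. The calls turned as well: on that scale the lowest set held 116 higher and 255 lower calls, and the highest 104 and 16.

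**Figure D1:**
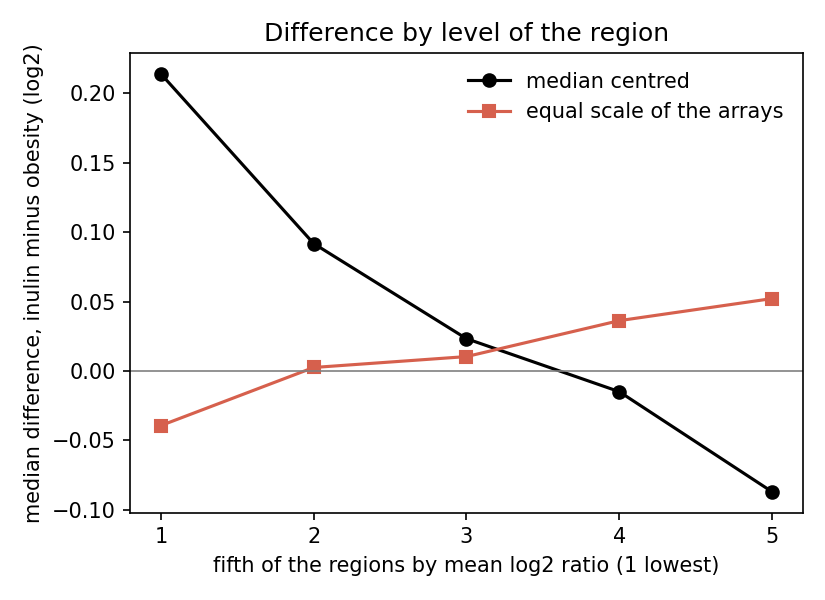
Median difference in log2 ratio, inulin minus obesity, against 5 equal sets of the regions ordered by mean log2 ratio, with median centring (circles) and with equal scale (squares). With median centring the difference runs from 0.21 in the lowest set to -0.087 in the highest, and on an equal scale from -0.039 to 0.052.

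The region with the largest higher ratio lay on chromosome 7 from 93942782 to 93944069. Its log2 ratio was -0.39 ± 0.24 in the inulin group and -2.0 ± 0.41 in the obesity group (SD, n = 3 each; limma difference 1.61, SE 0.19, adjusted p = 0.0145). The next were chromosome 9 from 20085495 to 20087026 (difference 1.26), chromosome 17 from 40862844 to 40864432 (1.24) and chromosome 3 from 59663678 to 59665401 (1.19). In 9 of these 10 most raised regions the input signal differed by more than the MeDIP signal. The exception was chromosome 17 from 46968582 to 46969460, where the ratio differed by 1.15, the MeDIP signal by 1.19 and the input signal by 0.049. The others were chromosome 2 from 86173012 to 86174650 (1.14), chromosome 9 from 38207996 to 38209666 (1.08), chromosome 2 from 111261509 to 111262336 (1.05) and chromosome 6 from 132751619 to 132753195 (1.01). At the region on chromosome 9 from 19244086 to 19245615 the MeDIP signal was not well above background in either group, so no difference is given. In all 10, fewer than 50% of the probes were measured above background in the MeDIP channel. The sizes depended on the processing. The difference on chromosome 7 was 0.45 with normexp, where the largest of these 10 was 0.52, on chromosome 17 from 46968582 to 46969460. Over probes with input above background, the difference on chromosome 7 was 1.09, and those on chromosome 9 from 20085495, chromosome 17 from 40862844 and chromosome 6 from 132751619 were 0.58, 0.50 and 0.55. There the differences on chromosome 9 from 38207996 (0.30) and on chromosome 17 from 46968582 (1.24, the largest of the 10) no longer passed the threshold, and the 2 on chromosome 2 had no value. Of the 10, only the region on chromosome 17 from 40862844 had a value over probes above background in both channels. Over the 20 named regions of both directions, 18 differences were smaller by over 1.5 times with normexp. The offset of 50 that normexp adds to both channels makes the ratios of dim spots smaller by construction. Smaller sizes with normexp are therefore no test of the differences. Calls were lost at 3 of the 20 with normexp, 4 on an equal scale, 5 after quantile normalization, 12 in the authors' deposited table and 13 with the median of the probes.

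The region with the largest lower ratio lay on chromosome 5 from 14943996 to 14945649. Its log2 ratio was -1.99 ± 0.16 in the inulin group and -1.26 ± 0.43 in the obesity group (SD, n = 3 each; limma difference -0.73, SE 0.19, adjusted p = 0.0494). There the MeDIP signal was higher in the inulin group by 0.34 and the input signal by 1.08. It was 1 of 9 neighbouring regions, from 14914398 to 15221207, whose input signal was higher in the inulin group by 0.84 to 1.71. Differences of -0.68 to -0.58 were measured at the other 9 regions. They lay on chromosome 8 from 96334379 to 96334951, chromosome 11 from 78001326 to 78002714, chromosome 2 from 30033486 to 30034146 and chromosome 6 from 18119387 to 18119846. On chromosome 7 they lay from 104473975 to 104474442, from 7251798 to 7252339 and from 12845529 to 12845998. The remaining regions lay on chromosome 4 from 107473567 to 107475131 and chromosome 17 from 28905939 to 28906661. At 5 of the 10 the MeDIP signal moved the opposite way to the ratio, and in 8 the input signal differed by more than the MeDIP signal. Fewer than 50% of the probes were measured above background in the MeDIP channel at 2 of them, on chromosome 6 and on chromosome 7 from 12845529. On chromosome 6, 0 of the 3 probes were above background on all 3 inulin arrays. None of the 20 named regions stayed past the threshold in every fit that left out 1 array, and 0 did so with slide as a random block.

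**Figure D2:**
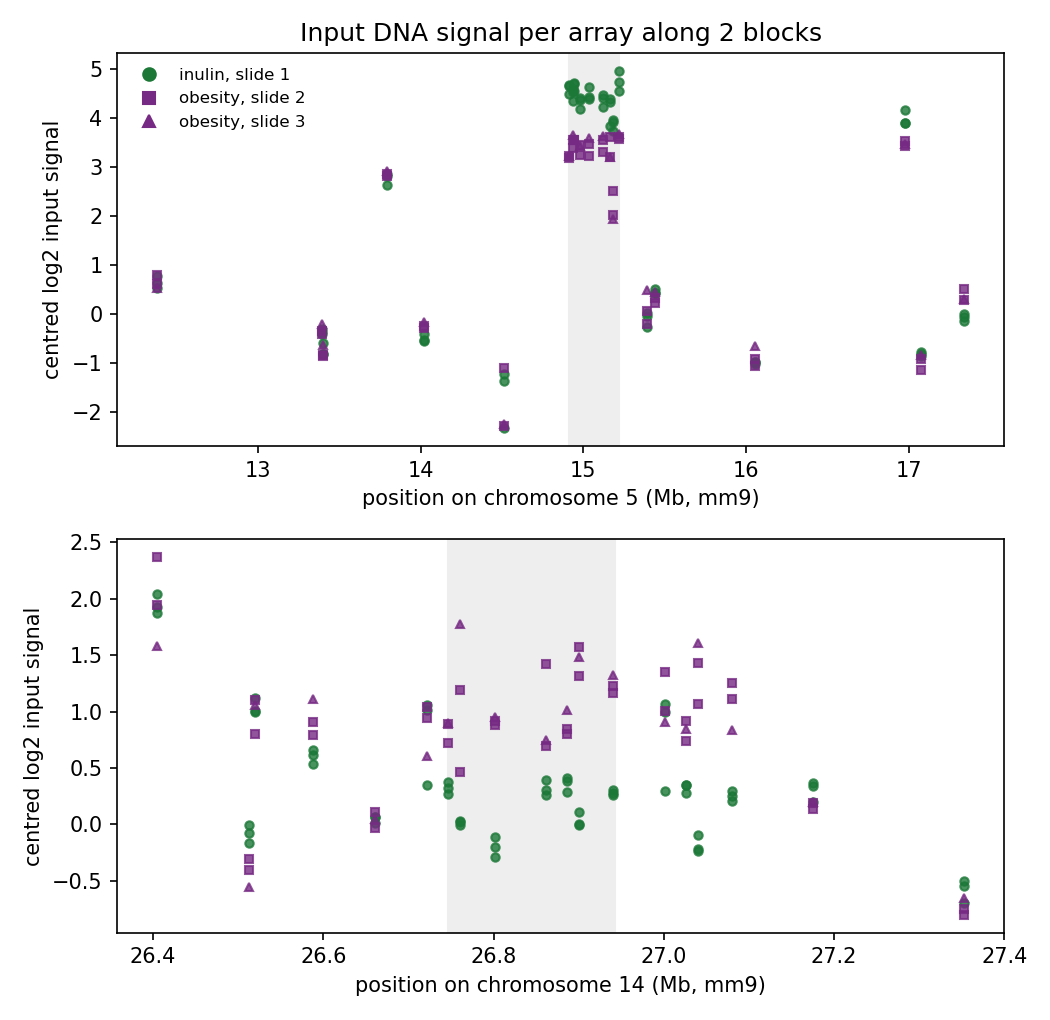
Centred log2 input signal of each region (1 point per array) against position in Mb on chromosome 5 and chromosome 14 in mm9, coloured by group with symbols for the slide; shading marks 2 runs of neighbouring regions. In the shaded run on chromosome 5 the input differences, inulin minus obesity, are 0.84 to 1.71, and in that on chromosome 14 they are -1.42 to -0.52, with 3 further regions past it at -0.51, -1.55 and -0.81.

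Over all 1675 called regions the input signal differed by more than the MeDIP signal in 892 (53.3%), against 49.1% of all 22574 regions. The share was 49.6% of the higher calls, close to that of all regions, and 64.5% of the lower calls. In the higher regions the median MeDIP difference was 0.24 and the median input difference -0.22. In the lower regions these were -0.11 and 0.27. With the input channel tested alone, 482 regions passed the threshold, of which 116 were among the 1675 (81 higher, 35 lower). With the MeDIP channel alone 57 did, of which 7 were among the 1675 (5 higher, 2 lower). The channels were closer at an unadjusted p under 0.05 (limma), with 5501 regions on the input and 4746 on the MeDIP channel. Single probes past the adjusted threshold numbered 23274 on the input and 18048 on the MeDIP channel. The tests of each channel alone were chosen after the data were seen.

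**Figure D3:**
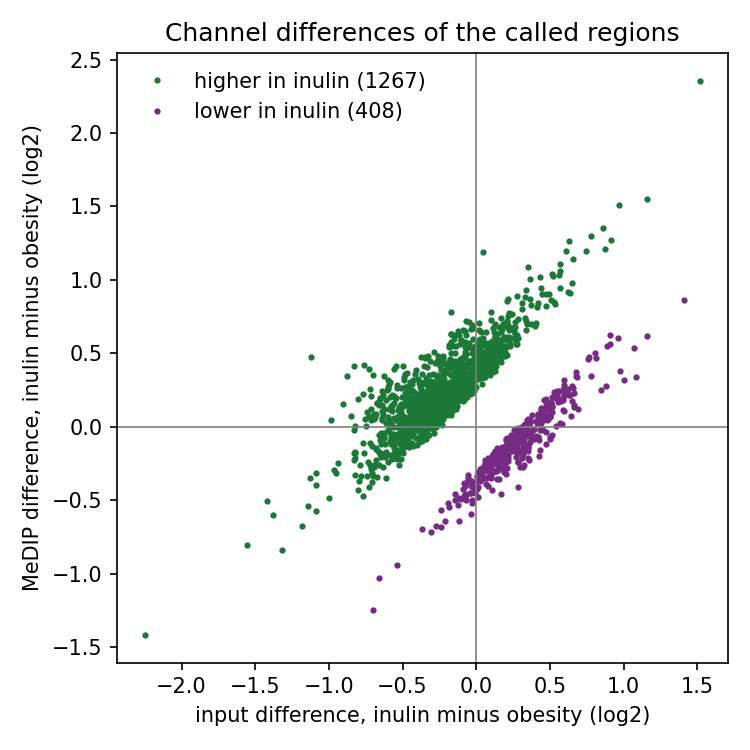
MeDIP difference against input difference, inulin minus obesity in log2 units, for the 1267 regions called higher and the 408 called lower, 1 point per region. The input signal differed by more than the MeDIP signal in 892 of the 1675 regions.

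Calls were spread unevenly over the chromosomes, in tests by chromosome and by window that the plan made beforehand did not hold. Chromosome 7 had 160 higher calls among 2087 regions (7.67%; Fisher's exact test, two-sided, adjusted p = 0.00171 over 42 tests) and chromosome 2 had 137 among 1905 (7.19%; adjusted p = 0.0211). Chromosome 11 had 49 lower calls among 1664 regions (2.94%; adjusted p = 0.00784) and fewer higher calls (61, 3.67%; adjusted p = 0.00422). There were also fewer higher calls on chromosomes 8 (34, 3.26%; adjusted p = 0.00586), 15 (30, 3.50%; adjusted p = 0.0349) and 12 (23, 3.34%; adjusted p = 0.0414). None of these 7 differences passed on an equal scale, where their adjusted p ran from 0.196 to 0.996. On that scale chromosome 16 had fewer lower calls (3; adjusted p = 0.0344) and chromosome 7 had 114 lower calls (adjusted p = 1.53e-24), of which 64 lay from 20 to 24 Mb, a stretch with 116 of its 2087 regions. In windows of 2000000 bp, 21 of 1038 held more higher calls than the rest of the genome at an adjusted p under 0.05, and 0 held more lower calls. The leading windows were chromosome 2 from 86 to 88 Mb, with 36 of 102 regions higher, and chromosome 4 from 60 to 62 Mb, with 16 of 22. On an equal scale the chromosome 2 window had 10 of 102 regions higher (Fisher's exact test, adjusted p = 0.0252). Its input was dim, with a median centred log2 signal of -1.37. The mean probe length there was 56.7 bp, against 49.2 bp over all regions. Its median input difference was -0.20, lower in the inulin group at 79 of the 102 regions, and its median MeDIP difference was 0.16. The chromosome 4 window was not among the 5 past the threshold on that scale, and its median difference was 0.061 there against 0.48 with median centring. On an equal scale the window on chromosome 7 from 22 to 24 Mb had 35 of 51 regions lower. Its median difference was -0.45 on an equal scale and 0.17 with median centring, so its direction turned with the scaling. The regions of this window were bright in the input and low in ratio, with median levels of 2.95 and -2.88 in centred log2 units. Those of the chromosome 4 window had median levels of 2.60 and -1.96. Neighbouring regions are not independent, so these p-values are too small.

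At single probes, 13956 of 170019 tested passed the threshold, 8712 higher and 5244 lower in the inulin group (limma), with 51160 at an unadjusted p under 0.05. Higher and lower probes numbered 13185 and 8030 with loess, 2927 and 3040 on an equal scale, 2179 and 2419 after quantile normalization, 13640 and 13450 with normexp, and 2107 and 2725 in the authors' deposited table. With slide as a random block 270 probes passed. Without inulin array 1, 2 or 3 there were 925, 701 and 2224, and without obesity array 1, 2 or 3 there were 5092, 15200 and 5808. Of the higher probes, 32.7% were not well above background in the MeDIP channel on any array, against 5.47% of the lower probes and 12.8% of all probes tested. The longest probes, of 60 bp, made up 45.6% of the higher probes, 2.78% of the lower probes and 13.4% of all tested. Among the 6 probes with the lowest p, 3 per direction, only Ch_220697_0109260 on chromosome 4 from 116806267 to 116806311 had a MeDIP signal above background. Its log2 ratio was 1.58 ± 0.086 in the inulin group and 2.97 ± 0.018 in the obesity group (SD, n = 3 each; limma difference -1.39, adjusted p = 0.00497). The difference was -0.49 with normexp and -0.90 on an equal scale, and it did not pass the threshold in the authors' deposited table (limma, adjusted p = 0.126; 0.000578 to 0.126 over the alternatives). The input signal of this probe was well above background on only 3 of the 6 arrays, which limits its ratio. Its region did not pass the threshold (difference -0.27, limma adjusted p = 0.101). The other 5 had no MeDIP signal well above background on any array, so no difference is given.

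The second comparison asked whether the spread of the ratios differed, as a change in the enrichment or in global methylation would show. The interquartile range of the log2 ratio was 1.38 ± 0.0076 on the inulin arrays and 1.73 ± 0.14 on the obesity arrays (SD, n = 3 each), without overlap. The difference was -0.36 (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 arrays allow). Each slide held arrays of 1 group, so no value within a slide can be had. In the authors' deposited table, whose arrays have almost the same distribution, the difference was 0.015. With normexp it was -0.23. The input signal alone also had a narrower interquartile range on the inulin arrays, 2.32 ± 0.033 against 2.42 ± 0.058. For the MeDIP signal it was 2.98 ± 0.098 against 3.17 ± 0.067, and neither overlapped (exact permutation p = 0.1 for both). The narrower spread was thus not confined to the enriched DNA.

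**Figure D4:**
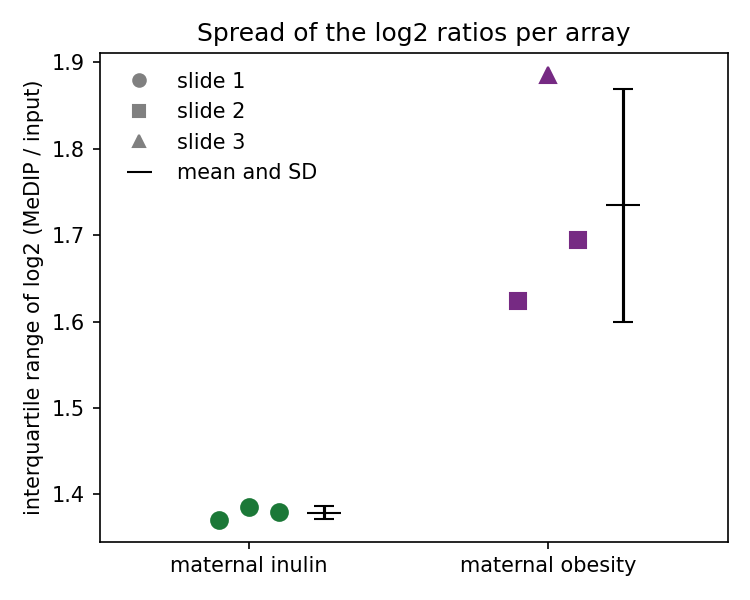
Interquartile range of the log2 MeDIP over input ratio of each array, by group, with symbols for the slide and bars for the mean and SD of 3 arrays. The inulin arrays average 1.38 and the obesity arrays 1.73, and no slide holds both groups.

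The third comparison looked at the sex chromosomes, since the labels do not give the sex of the offspring. The median ratio of X probes relative to autosomal probes was -0.035 ± 0.039 in the inulin group and -0.048 ± 0.034 in the obesity group (SD, n = 3 each; exact permutation test, two-sided, p = 0.7). The difference, 0.013, was 0.042 with normexp (exact permutation p = 0.2), 0.00596 over probes with input above background and -0.0014 with loess (exact permutation p = 1 for both). The X input signal was -0.36 ± 0.035 and -0.35 ± 0.030 (exact permutation p = 0.8). Single arrays ran from -0.40 (inulin array 3) to -0.32 (obesity array 2), and the groups overlapped. As far as the number of X copies moves this signal, these values argue against unequal sexes in the groups. Over the 100 Y probes the ratio was -0.38 ± 0.072 and -0.59 ± 0.13, and the input signal -0.25 ± 0.16 and 0.12 ± 0.098, each without overlap (exact permutation p = 0.1 for both). The Y MeDIP signal was -0.47 ± 0.11 and -0.39 ± 0.10 (exact permutation p = 0.4). The difference in Y ratio, 0.21, was 0.11 over probes with input above background (exact permutation p = 0.4), 0.095 with normexp, 0.14 without obesity array 3 and 0.072 in the authors' deposited table.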

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

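The input channel, which the comparisons of the report use only as the lower part of the ratio, differed between the groups by itself. The tests on the input channel, on brightness and on the direction of the MeDIP signal, all the splits, and the limit set for the count on an equal scale were chosen only after the results were seen. The count on an equal scale itself and the test on probe length were not.

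On the input channel alone 482 regions passed the threshold, against at most 12 in the other splits of the 6 arrays. Those splits mix the groups and the slides, which widens the spread within each set. They therefore cannot tell hybridisation or labelling that also moves the input DNA from other differences between the groups. Such hybridisation or labelling may account for part of the 1675 regions called on the ratio, which stays open. Of these, 116 were also called on the input, but the input is part of the ratio, so some sharing is built in. Unequal spread as the whole cause stays open. On an equal scale 911 regions passed and 0 in any other split, where mixed groups widen the spread within each set. But the 911 still followed the mean ratio, in the reverse direction. The lowest of the 5 sets held 116 higher and 255 lower calls, and the highest 104 and 16. A single factor per array thus left a dependence on level, so this count does not settle the question. Of the 10 splits 1, the real one, gave as many regions (1675, highest other 0) and 1 as many probes (13956, highest other 0), but 10 splits are too few for a share under 0.05. Probe length, read as melting behaviour, stays open: the longest minus the shortest probes differed between the groups by 0.62 in the ratio without overlap, but by -0.16 on the input with overlap, which among 3 arrays sets no bound, so the limit written beforehand was too weak. Maternal diet and slide both stay open, because no slide held both groups.

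Along the chromosomes, 2 blocks of at least 4 neighbouring regions differed in input signal by at least 0.5 in 1 direction without overlap of the groups, a rule set after both places had been seen. On chromosome 5 from 14914398 to 15221207, 9 regions had a median input difference of 1.06 (0.84 to 1.71) and a median MeDIP difference of 0.70. On chromosome 14 from 26746165 to 26942515, 7 regions had a median input difference of -0.96 (-1.42 to -0.52) and a median MeDIP difference of -0.51. The neighbours of the chromosome 5 block differed by 0.24 and -0.21, and those of the chromosome 14 block by -0.058 and -0.30. The chromosome 14 pattern did not end there: past the region at -0.30, the next 3 regions differed by -0.51, -1.55 and -0.81. The layout of regions recurs along this stretch. Regions of 10 probes start at 26746165, 26885918 and 27025534, and regions of 5 probes at 26760727, 26900480 and 27040090. These regions may therefore not be separate measurements, which was not tested.

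For the chromosome 14 block, a slide or hybridisation difference that acts by brightness alone is argued against, since the 3535 regions elsewhere with the same input signal differed by a median of 0.052 (quartiles -0.083 and 0.19), which the choice of the blocks does not set. For the chromosome 5 block it stays open: 132 such regions differed by a median of 0.026 (quartiles -0.20 and 0.33), but only 6 of them lay in the middle 50% of the block's signal, and the 13 bright regions from 26 to 28 Mb of that chromosome differed by a median of 0.48, 11 of them higher in the inulin group. The MeDIP signal moved the same way in 100% of the block regions, as more or fewer DNA copies in the animals of 1 group would give. But over all 22574 regions the channels moved opposite ways, each adding to the ratio, in only 6439, so moving together is common. A difference in copy number between the animals is a candidate explanation, which this share hardly sets apart from others. A sequence variant, and a slide effect on these particular sequences, would move both channels too and were not tested. Of the 10 splits of the arrays 1, the real one, gave as many regions in blocks (16, highest other 0), but the rule was made on that split, and 10 splits are too few for a share under 0.05.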

How the results depend on the processing

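The position block, the filter on both channels, each channel alone, equal scale with slide, and the gene-by-gene weights were chosen after the data were seen; the cause of the changes below was not tested. The 1675 regions became 2798 with loess, 911 on an equal scale, 497 after quantile normalization, 582 in the authors' deposited table, 0 with slide as a random block (4049 at an unadjusted p under 0.05, limma) and 0 with a position block (5118 unadjusted). They became 6855 with array weights, 4341 with gene-by-gene weights, 3986 at a threshold of 0.1, 733 with the median of the probes, 480 on an equal scale with slide as a random block, 57 on the MeDIP channel and 482 on the input channel. The 13956 probes became 27090 with normexp, 21215 with loess, 5967 on an equal scale, 4598 after quantile normalization, 4832 in the deposited table, 270 with slide as a random block, 294 with a position block, 43332 with array weights, 33393 with gene-by-gene weights, 23719 with a robust prior and trend, 32384 at a threshold of 0.1 and 23274 on the input channel. On the MeDIP channel 18048 probes passed. Leaving out 1 array gave 0 to 2171 regions and 701 to 15200 probes. With the replicate block, 2699 regions and 14747 probes passed. The same-numbered arrays correlated at -0.14, 0.28 and 0.33 in their deviations. Inulin arrays 2 and 3 correlated best with their own number and inulin array 1 did not. So few values do not show whether the numbers pair the arrays.

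The difference in spread was 0.015 in the deposited table and -0.41 to -0.28 with 1 array left out. The X difference, 0.013, turned to -0.0014 with loess, was 0.042 with normexp (exact permutation p = 0.2) and 0.00596 over probes with input above background, and ran from -0.0072 to 0.031 with 1 array left out, at -0.0072 without inulin array 3 and -0.0066 without obesity array 2. Each of the 20 named regions kept its direction in every alternative on the ratio that gave it a value, while on the MeDIP channel 5 of the 10 lower regions turned. The alternatives for genes, gene lists and probe classes were not run, since no annotation of the build was used here. Dim signal limits the rest: 127435 of 174638 probes were well above background in both channels on all arrays.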

Other observations

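The tests on slide and on maternal diet, and the limit set for the share of higher calls, were chosen only after the results were seen.

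Across 6 normalizations, 113 regions passed the threshold each time, 69 higher and 44 lower in the inulin group. In 60 of these, 48 higher and 12 lower, the MeDIP signal moved more than the input signal and in the same direction as the ratio. Over all 22574 regions the input signal moved more in 49.1%, so 60 of 113 is near the share of all regions. That pooled share joins 48 of 69 higher regions, which lie above the share of all regions, and 12 of 44 lower regions, which lie below it. These shares were not tested. In the region of these 60 with the largest rise in ratio, chosen after its values were seen, all 8 probes had MeDIP signal above background on every array. It lay on chromosome 4 from 41761994 to 41763751, with a log2 ratio of 0.12 ± 0.32 in the inulin group and -0.70 ± 0.18 in the obesity group (SD, n = 3 each; limma adjusted p = 0.0239). Its MeDIP signal differed by 0.48 and its input signal by -0.33, so both channels added to the difference. In another, on chromosome 6 from 144157596 to 144159125 and also chosen after its values were seen, all 7 probes were above background and the ratio was -0.12 ± 0.13 and -0.77 ± 0.054 (SD, n = 3 each; limma adjusted p = 0.0146). There the MeDIP signal differed by 0.66 and the input signal by 0.020. The normalizations share the slides, so they do not bear on a slide effect.

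The narrower ratios of the inulin arrays did not come from the background handling of Feature Extraction alone: with normexp the lowest obesity range still lay 0.13 above the highest inulin range. Nor did dim MeDIP probes held up by a floor account for it, with a gap of 0.20 over probes above background in both channels. Whether the unequal spread accounts for the excess of higher calls stays open. Their share came to 53.2% on an equal scale, but also to 53.5% with normexp and 45.8% over probes above background in both channels, where the spread still differed by -0.23 and -0.28 without overlap. Slide and maternal diet cannot be told apart, because no slide held both groups: the groups differed by 0.36 and the obesity arrays of different slides by 0.23.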
